A study of Drosophila melanogaster with 2 samples.

How the data were processed

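The series holds 2 libraries of simplified Hi-C from Drosophila melanogaster embryos of the Oregon-R w1118 genotype. In Hi-C and related 3C methods, chromatin is fixed with formaldehyde, cut with a restriction enzyme and ligated in dilute solution, so that DNA fragments lying near each other in the nucleus are joined and can be counted as contacts by paired-end sequencing. Per the labels' protocols, nuclei were cut with Dpn II, ligated with T4 DNA ligase, and the purified DNA was sonicated and made into paired-end libraries, with no enrichment of ligation junctions named. One library, called the pilot library here, is labelled as embryos of 4 to 12 hr and was sequenced on 7 lanes of a GA-II. The other, called the deep library, is labelled as embryos of 16 to 18 hr and was sequenced on 7 lanes of a HiSeq. The growth protocol of both samples gives 16 to 18 hr, so the age of the pilot library is stated differently in its own labels, and ages are given here as in the age label.

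The authors deposited, for each library and each of 5 bin sizes (10, 20, 40, 80 and 160 kb), a table of bin pairs with an observed count and an expected count. The observed count is, per the file headers and the values, a whole number of contacts per pair of bins, not normalized, with the pairs of different bins listed in both orders. The expected count is a model value the authors computed for each bin pair. In the deposited tables this expected count did not fall with distance along the chromosome, and it was halved for a bin with itself, so it holds differences between bins and not the effect of distance. The model behind it, the mapper and the read filters are not given in the sources used here. The bin tables also hold a count per bin that the authors deposited without saying what it is, and only the coordinates of those tables were used. The genome build is dm3, per the submitters' processing notes, with the arms 2L, 2R, 3L, 3R, 4 and X. Positions are given in dm3, counted from 1. The 80 kb and 160 kb tables held all pairs of bins, whereas the 10, 20 and 40 kb tables held pairs of the same arm up to 0.8, 2 and 10 Mb apart.

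All further values were computed from these tables with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Each pair of different bins was counted once. A ratio is a sum of observed contacts over a sum of expected contacts. Ratios between arms and between ends of arms were divided by the ratio over all pairs of bins on different chromosomes of the same library. Contacts within a bin entered the shares of contacts and no other result.

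The decay with distance was the slope of log10 of this ratio on log10 distance over 12 distance classes from 0.2 to 5 Mb, from 40 kb bins. For the alignment of arms, pairs of bins whose distances from the centromeric ends of their arms differ by at most 2 Mb were set over pairs that differ by 10 Mb or more. The centromeric end is the high coordinate of 2L, 3L and X and the low coordinate of 2R, 3R and 4. Centromeric ends were the 2 Mb next to it and telomeric ends the 1 Mb at the other end. These are ends of the assembled sequence, and the heterochromatin beyond them was not analysed here. Domain boundaries came from an insulation score in 20 kb bins, the log2 ratio of contacts across a position over contacts within its sides, 5 bins each side. A boundary was the lowest score within 5 bins each side that lay at least 0.5 below the highest score within 10 bins on both sides. For values corrected for distance, the expected contacts of an arm were multiplied by the ratio of its pairs at that distance, pooled over distances within 5%. Compartments were the first eigenvector, per arm and in 80 kb bins, of the correlation matrix of the log2 of these values with a pseudocount of 0.5. No dm3 gene annotation was used here, so the eigenvectors were not oriented by gene density. Their signs were set between arms from contacts between arms of the same library, and the end with more contacts with other chromosomes was called positive. That overall sign is a convention, set although the eigenvectors were first planned to be left unoriented. A mean correlation of eigenvectors between the libraries was therefore given a positive sign in every alternative; this was decided after the mean in 160 kb bins had come out negative (its size is 0.550) because the convention had turned all arms of 1 library. The strength of the pattern was measured on contacts between chromosomes of the other library, as contacts within the top and within the bottom of 5 rank classes over contacts between top and bottom.

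Polycomb proteins repress developmental regulator genes, and contacts were computed between 21 loci known as their targets. The intervals of these loci are approximate and were written from general knowledge of dm3, not from an annotation, so each value belongs to the 80 kb bins named by position and may miss part of a gene. The spacing of the intervals was checked against the order and spacing of the same genes in a RefSeq table of Release 6, without using its coordinates. For 2 of the 21 loci, salm-salr and tsh-tio, an edge differed by more than 50 kb, by at most 126 kb, and for the other loci by at most 29.8 kb. Lists of other gene families (ribosomal protein, proteasome, Osiris, cuticle, odorant and gustatory receptor, Jonah and histone genes) had been set for the eigenvector, and were not run because positions in dm3 were not given in the tables used here. For the same reason boundaries and bins are named by position and not by gene.

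There is 1 library per group. No test between the groups was made, no p-value is given, and embryo age, depth and sequencer differ together between the libraries and cannot be told apart. Errors are of 3 kinds, all within a library. The standard error (SE) of a ratio or slope comes from a jackknife that leaves out each block of 2 Mb in turn. It covers the spread over the genome and not the spread between embryos or libraries. Because arm 4 is a single block, its SE leaves out variation within arm 4. The 95% interval of such a ratio is that of a normal distribution. Ratios of single pairs of loci, bins or ends have exact 95% Poisson intervals, and shares of contacts 95% Wilson intervals. These cover counting error only. No molecular identifiers are named, and whether duplicate reads were removed is not given in the sources used here. Percentiles come from 10000 random rotations of positions along the arms, which keep spacing, and describe these libraries only.

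The items named follow a rule. They are all 21 loci, the 10 boundaries with the lowest score in the deep library that lie within 1 bin of a pilot boundary, the 10 pairs over 1 Mb apart on an arm, and the 10 pairs on different chromosomes, with the highest ratio in the deep library. These pairs of 80 kb bins needed at least 20 observed contacts, bins with expected totals over the median divided by 3, and a ratio above 1 in the pilot library too. The rule, the comparisons and most alternatives were fixed before the data were examined. Windows of matched size and distance were taken for 5 pairs of loci; those other than ANT-C with BX-C were chosen after their values were seen. The alternatives were other bin sizes, observed contacts without the expected, matrix balancing (expected contacts rescaled so that each bin's observed and expected totals agree), leaving out bins with low expected totals or near the ends of arms, other settings of the boundary score, and the deep library thinned at random to the pilot total, in 20 draws for the excess over 1 of pooled contacts.

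The slope, arm pairs, alignment, ends, eigenvectors, locus pairs and boundaries were tested on simulated data. These data were drawn from the expected counts of each library with known changes and the library's own total. Shares of contacts, agreement between libraries, the later tests of explanations and the errors were not simulated. In the deep library, a simulated slope of -0.8 was recovered as -0.80, a 2L-2R ratio of 1.5 as 1.50, an alignment of 1.3 as 1.30 and a ratio of telomeric ends of 2 as 2.01. A ratio of ANT-C with BX-C simulated at 2.5 was recovered as 2.48 in the deep and 2.76 in the pilot library. A median over pairs of loci on different chromosomes simulated at 1 came out at 1.01 in the deep and 0.896 in the pilot library, where the pairs held few contacts. Of the simulated boundaries, 99.1% were found within 1 bin in the deep library and 96.7% in the pilot library. Of the boundaries called in simulated data, 99.1% and 92.4% lay at a simulated one. Contacts within over across domains were simulated at 2, against 1.53 and 1.57 in the real libraries, so these shares may not hold for them.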

Results

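Contacts between parts of the Drosophila genome were measured in 2 embryo libraries, 1 pilot library of embryos labelled 4 to 12 hr and 1 deeply sequenced library of embryos labelled 16 to 18 hr. The 80 kb tables held 2607453 contacts in the pilot library and 15221346 in the deep library, 5.84 times as many. At this depth 43.3% of pairs of 80 kb bins had no contact in the pilot library, against 7.3% in the deep library. Values are given for each library on its own, with errors within that library. The question was how the chromosome arms of the fly are folded and placed relative to each other.

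Contacts within a chromosome arm, those inside a single 80 kb bin included, made up 69.5% of all contacts in the pilot library (95% Wilson interval 69.4 to 69.5%) and 80.6% in the deep library (80.5 to 80.6%). Contacts between the arms of chromosome 2 or of chromosome 3 made up 7.37% in the pilot and 5.62% in the deep library, and contacts between different chromosomes 23.2% and 13.8%. The pilot library held a larger share of contacts between chromosomes, but also a larger share within single 80 kb bins, 40.7% of all contacts against 26.8%. Of the contacts between different bins, 48.5% joined bins of the same arm in the pilot and 73.4% in the deep library, and 39.1% and 18.88% joined different chromosomes. The differences between the libraries exceeded counting error, and with 1 library per group they have no replicate check.

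Within arms, contacts fell with distance on 2L, 2R, 3L, 3R and X, and X had fewer contacts than the autosomal arms at every distance measured. The slope of log10 contact ratio on log10 distance from 0.2 to 5 Mb had a mean over the 4 long autosomal arms of -0.723 in the pilot library (SD 0.0252, n = 4 arms) and -0.786 in the deep library (SD 0.0183, n = 4 arms). The slope of X was -0.714 (SE 0.0192) and -0.752 (SE 0.0262), which differed from the autosomal mean by 0.00949 (SE 0.0226) and 0.0346 (SE 0.0315), both intervals holding 0. In the deep library the ratio of observed to expected contacts at 219 kb was 59.0 on X against a mean of 87.2 on the autosomal arms (SD 4.64, n = 4 arms, lowest 81.7). At 4400 kb it was 6.06 against 7.68 (SD 0.238). X over the autosomal mean lay between 0.788 and 0.830 in the 12 distance classes of the pilot library and between 0.674 and 0.788 in those of the deep library. With 0.4 to 10 Mb as the range, the mean autosomal slope was shallower, at -0.603 in the pilot and -0.667 in the deep library.

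**Figure D1:**
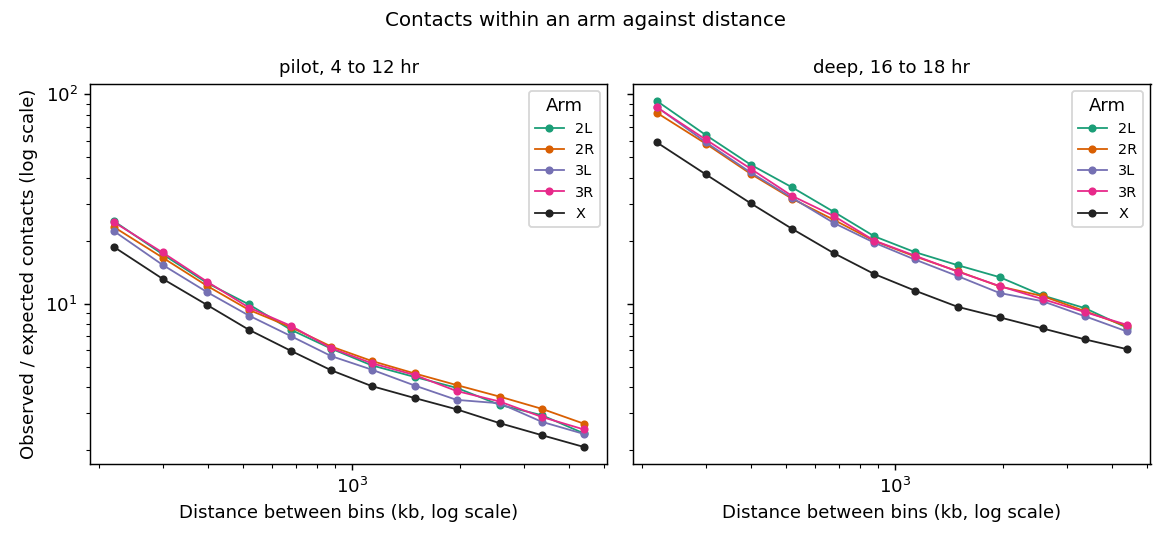
Observed over expected contacts (log scale) against the distance between 40 kb bins in kb (log scale), for the arms 2L, 2R, 3L, 3R and X, in the pilot library on the left and the deep library on the right, each point a distance class. X runs below the 4 autosomal arms in both libraries, at 59.0 against a mean of 87.2 at 219 kb in the deep library.

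Among the long arms, the left and right arms of the same chromosome contacted each other more than arms of different chromosomes did. Relative to all pairs on different chromosomes, 2L with 2R had a ratio of 1.34 (SE 0.0333) in the pilot and 1.71 (SE 0.0920) in the deep library, and 3L with 3R had 1.23 (SE 0.0327) and 1.504 (SE 0.0659). X had fewer contacts than average with each long autosomal arm, from 0.886 with 2L to 0.949 with 2R in the pilot library and from 0.838 with 3R to 0.922 with 2R in the deep library. The interval of X with 2R in the deep library reached 1.01. The small chromosome 4 had more contacts than average with 2L, 2R, 3L and 3R, between 1.17 and 1.25 in the pilot and between 1.43 and 1.65 in the deep library, and with X 0.975 and 1.08, intervals holding 1. With matrix balancing chromosome 4 with X was at 1.47 and 1.67, and without the expected at 0.613 and 0.956. Without the expected contacts, chromosome 4 with the autosomal arms turned below 1 in the pilot library, between 0.636 and 0.770, and X with 2R turned to 1.04. Pilot X with 2L, 3L and 3R stayed below 1 without them, at 0.864, 0.918 and 0.972. With matrix balancing the deficit of X was gone or nearly so: X with 2L, 2R, 3L and 3R was at 1.00, 0.996, 1.03 and 0.975 in the pilot library and at 0.9998, 1.11, 1.06 and 0.977 in the deep library.

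Bins at similar distances from their centromeric ends contacted each other more than bins at different distances. Over all pairs of long arms, pairs of bins aligned within 2 Mb had 1.195 times (SE 0.0371) the contacts of pairs offset by 10 Mb or more in the pilot library and 1.25 times (SE 0.0743) in the deep library. The ratio was 1.37 (SE 0.109) for 2L with 2R and 1.38 (SE 0.0880) for 3L with 3R in the pilot library. In the deep library it was 1.41 (SE 0.241) for 2L with 2R, with an interval from 0.939 to 1.88, and 1.43 (SE 0.172) for 3L with 3R. Between long arms of different chromosomes it was 1.14 (SE 0.0335) and 1.18 (SE 0.0654).

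Telomeric ends contacted each other across chromosomes, and chromosome 4 contacted the centromeric ends of the other arms as a pool. Bins in the last 1 Mb before the telomeric ends had a ratio of 1.74 (SE 0.199) in the pilot library and 3.32 (SE 1.01) in the deep library. The ratio was higher nearer the end, at 2.52 and 7.26 in the last 0.5 Mb, and lower without the last 0.2 Mb, a choice made after seeing the data, at 1.60 and 2.31. Whether reads shared by repeats near the ends add to the ratio was not tested. Chromosome 4 with the centromeric ends had 1.83 (SE 0.224) and 3.836 (SE 0.566), and with the telomeric ends 1.04 (SE 0.0748) and 1.10 (SE 0.0593). With matrix balancing the pilot ratios of chromosome 4 were 2.55 with the centromeric and 1.30 with the telomeric ends. Ratios of ends were not computed without the expected, where pilot ratios of chromosome 4 with whole autosomal arms turned below 1. Centromeric with telomeric ends had 0.878 (SE 0.0527) in the deep library and 0.964 (SE 0.0783) in the pilot library, and with ends of 1 and 0.5 Mb 0.994 and 1.13. Pooled over different chromosomes, centromeric ends had ratios of 1.31 (SE 0.282) and 1.68 (SE 0.381), whose intervals held 1.

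Single pairs of ends, including those of the same chromosome, differed widely in the deep library. The centromeric ends of 2L and 2R, which flank 1 centromere, had a ratio of 9.33 (Poisson interval 9.12 to 9.56, 7034 contacts), 3L and 3R 3.44 (3.32 to 3.56), and 2R and 3L 3.19 (3.05 to 3.34). The highest ratio of chromosome 4 was with the centromeric end of 3L, at 6.30 (6.09 to 6.52), and its lowest with that of X, at 1.67 (1.58 to 1.76), where the pilot ratio was 0.953 (0.791 to 1.14). In the pilot library chromosome 4 with 3L was not the highest, at 1.98 (1.68 to 2.32), against 2.08 with 2L and 2R and 2.07 with 3R. With the long autosomal arms the centromeric end of X had ratios from 1.26 with 3R to 1.45 with 2R, and in the pilot library from 0.930 with 3R to 1.04 with 2R. Among telomeric ends, the highest ratio was that of 3L with 3R, the ends of chromosome 3, at 5.07 (4.88 to 5.26), the highest between chromosomes that of 2R with 3R, at 4.59 (4.40 to 4.78), and the lowest that of 2L with X, at 1.68 (1.58 to 1.80). In the pilot library 2L with 2R was highest, at 2.60 (2.38 to 2.84), against 2.22 for 3L with 3R, and 2L with X was lowest, at 1.30. In the deep library the centromeric ends of 4 of the 5 long arms had fewer contacts with their own arm, 4 Mb or more from the end, than distance predicts, at 0.659 on 2R, 0.772 on 3L, 0.798 on X and 0.836 on 2L, and 3R was at 1.03. In the pilot library the values were 0.882 on 2R, 0.997 on 3L, 0.863 on X, 0.921 on 2L and 1.03 on 3R.

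**Figure D2:**
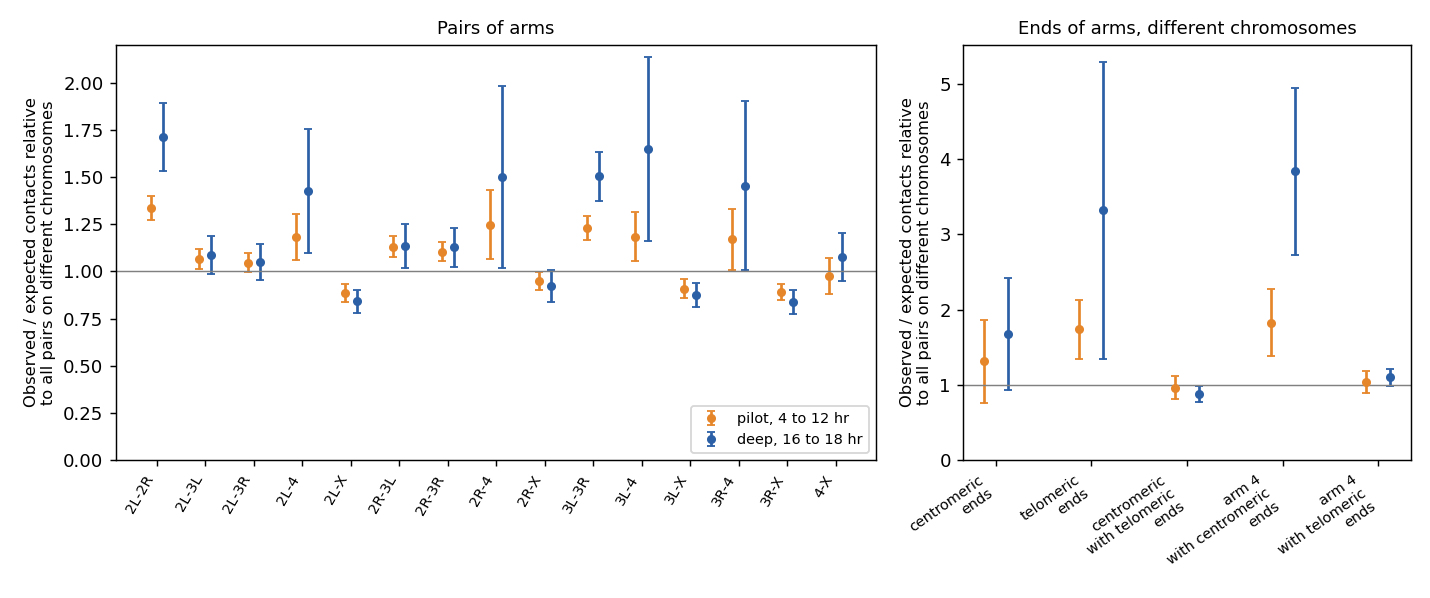
Observed over expected contacts relative to all pairs on different chromosomes, for each pair of arms on the left and for ends of arms on the right, pilot library in orange and deep library in blue, with bars of the 95% jackknife interval within a library and a line at 1. The pair 2L-2R stands at 1.34 and 1.71, and chromosome 4 with the centromeric ends at 1.83 and 3.836.

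Arms were divided into domains with similar boundaries in both libraries. The insulation score gave 458 boundaries in the pilot and 460 in the deep library, with a median spacing of 220 kb in each (quartiles 160 and 300 kb). A boundary had to be the lowest score within 5 bins each side, so number and spacing follow in part from that setting in both libraries. Of the boundaries of each library, 281 lay within 1 bin of a boundary of the other library, 61.4% of the pilot and 61.1% of the deep boundaries. After rotating the positions along the arms the median share was 23.1%, and 0 of 10000 rotations reached the observed share. The score correlated between the libraries across 5698 positions with a Pearson r of 0.733 and a Spearman rho of 0.729, positions not being independent replicates. At distances from 60 to 200 kb, deep-library contacts within a domain of the pilot library were 1.53 times those across a boundary (SD 0.0506, n = 5 arms), and pilot contacts at deep boundaries 1.57 times (SD 0.115, n = 5 arms).

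By the score of the deep library, the lowest of the boundaries present in both libraries lay on 3R between bins meeting at position 18180000, with a log2 score of -3.33 in the deep and -2.95 in the pilot library. Next was 2L at 10200000, with -3.28 and -2.47. The other named boundaries were on X at 9580000, 12660000, 15600000, 17800000 and 16180000 and on 3L at 15160000, 12720000 and 3040000. In the pilot library the lowest scores of the 10 were on X, with -3.41 at 12660000, -3.34 at 9580000 and -3.33 at 17800000. The pilot boundary lay at the same position in 9 of these 10, and 1 bin away for that on 3L at 3040000. With 10 bins each side the counts were lower, at 231 and 249, and with a depth of 1.0 they were 293 and 253.

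Beyond domains, the first eigenvector of each arm divided it into stretches with different patterns of contacts, whose position was shared between the libraries to a degree that differed by arm. The eigenvectors of the libraries had a Pearson r across 80 kb bins of 0.913 on X, 0.884 on 3R, 0.846 on 2L, 0.505 on 2R and 0.189 on 3L. On 2R, 3L and X the first eigenvector of the deep library was lower in the centromeric 2 Mb than in the rest, with means of -0.452 against 0.975 on 2R, -0.708 against 0.941 on 3L and -0.672 against 0.371 on X. Without the 2 Mb next to the centromeric ends, a choice made after seeing the data, r was between 0.799 and 0.897 on the 5 arms. The eigenvector held 4.01 to 6.09% of the variance per arm in the pilot library and 18.3 to 32.2% in the deep library.

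Across chromosomes, bins of the top rank class contacted each other more than bins of opposite classes did. For bins of the bottom class this held with pilot classes and deep contacts and not with deep classes and pilot contacts, 2 sets that differ in both. With classes from the pilot library and contacts from the deep library, both same classes pooled over opposite gave 1.32 (SE 0.0296), and the other way round it was 1.16 (SE 0.0680), or 1.31 (SE 0.0382) without the centromeric 2 Mb, 1.09 with matrix balancing and 1.04 in 160 kb bins. Because the end with more contacts with other chromosomes was called positive, a higher value of the top than of the bottom class in part restates that choice. The pooled ratio also rises where top bins have more contacts with all bins, so alone it does not show a preference of like for like. With deep classes and without the centromeric 2 Mb, 46585 of the 53658 pooled same-class contacts of the pilot library were top with top. Relative to all long-arm pairs on different chromosomes, top with top was 1.23 (SE 0.0328) in the deep library, bottom with bottom 0.969 (SE 0.0228) and top with bottom 0.865 (SE 0.0124). In the pilot library, with classes from the deep library, these were 1.18 (SE 0.0236), 0.789 (SE 0.0649) and 0.935 (SE 0.0413), and without the centromeric 2 Mb 1.29, 0.673 and 0.875, so bottom bins contacted each other less than they contacted top bins.

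**Figure D3:**
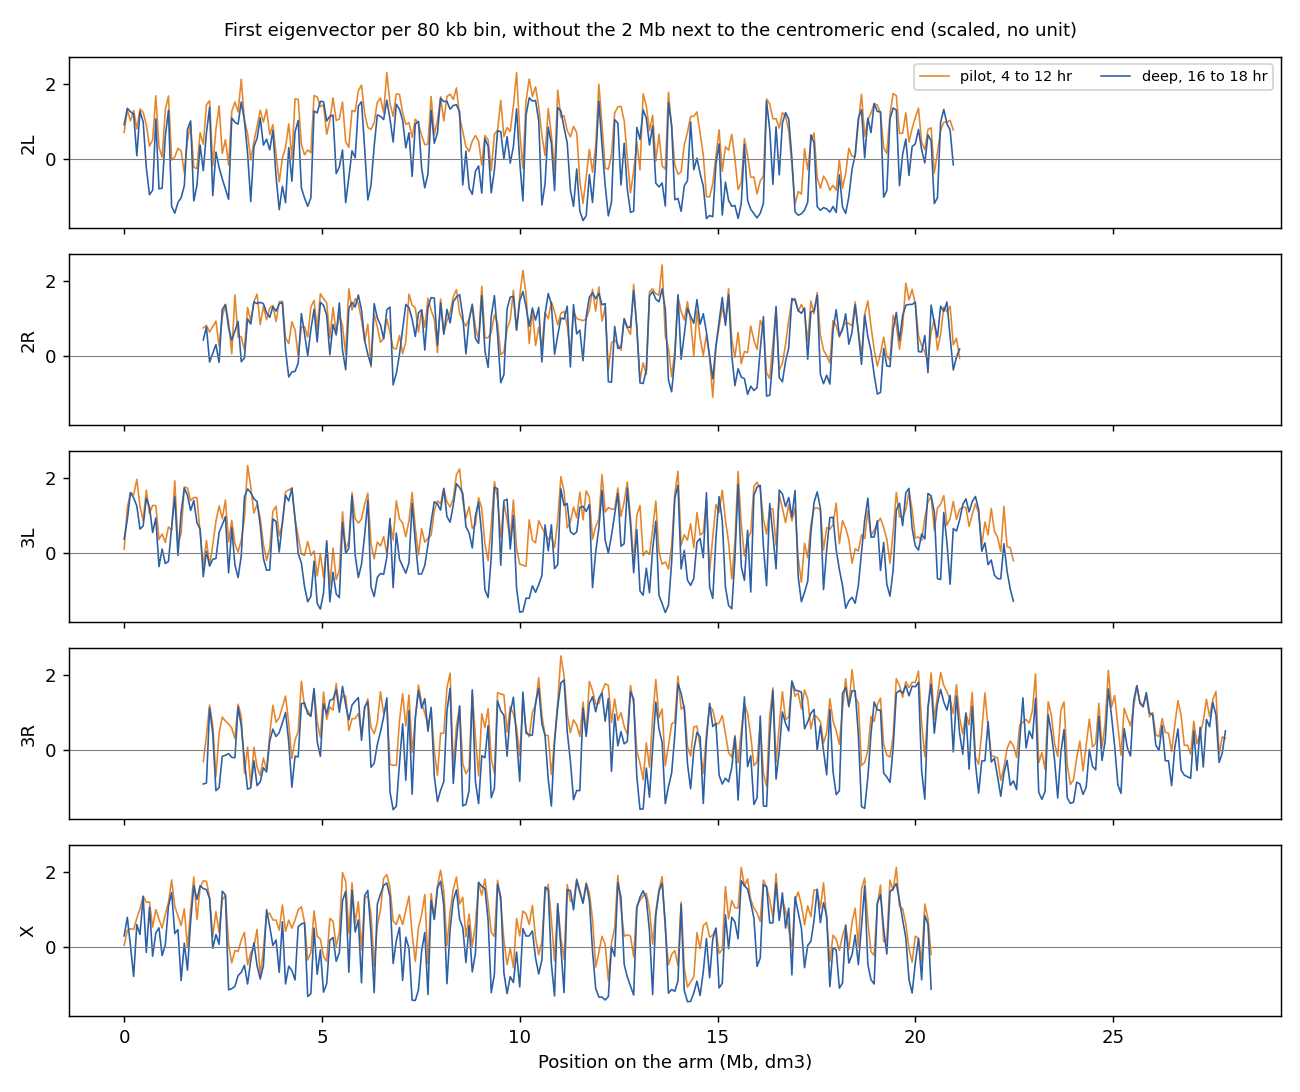
First eigenvector (scaled, no unit) of each 80 kb bin against position in Mb on 2L, 2R, 3L, 3R and X, without the 2 Mb next to the centromeric end, pilot library in orange and deep library in blue. Peaks and troughs of the libraries lie at the same places, with r between 0.799 and 0.897 per arm.

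Contacts between Polycomb target loci were examined first for the Hox gene clusters, the Antennapedia complex (ANT-C) and the Bithorax complex (BX-C), which set segment identity along the body and lie 10 Mb apart on 3R. In the deep library ANT-C (80 kb bins from 2480001 to 2880000) and BX-C (12480001 to 12800000) had 625 contacts, 2.29 times the number for their distance (Poisson interval 2.12 to 2.479). This was above 99.9% of 847 pairs of windows of the same size and distance on the 5 long arms. In the pilot library they had a ratio of 1.09, above 68.2% of such pairs. BX-C with the NK homeobox cluster around tin and slou (3R, 17200001 to 17440000), muscle and heart regulators, had 2.52 (2.36 to 2.70) in the deep and 1.51 (1.07 to 2.07) in the pilot library, and ANT-C with that cluster 1.59 (1.40 to 1.80) in the deep and 0.823 in the pilot library. Between even-skipped (eve) and Distal-less (Dll), a segmentation gene and a limb gene on 2R, the deep ratio was 2.37 (1.60 to 3.39, 30 contacts) and the pilot ratio 0.840. Between bifid (bi) and cut (ct) on X they were 1.75 (1.51 to 2.03) and 0.505. Against windows of the same size and distance, the deep ratios were above 99.9% for BX-C with the NK cluster, 97.3% for ANT-C with it, 98.8% for eve with Dll and 97.8% for bi with ct, and the pilot ratios above 97.3%, 29.1%, 55.0% and 11.39%. These pairs were chosen after their values were seen, so their high deep percentiles follow in part from that choice. Of the 56 pairs on the same arm, 1 had a pilot interval above 1, BX-C with the NK cluster.

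Over the 56 pairs of loci on the same arm the median ratio was 1.11 in the deep library, above 99.1% of rotated lists, whose median was 0.944. In 16 of the 56 pairs the interval lay above 1 and in 4 below. The 4 were ANT-C with hedgehog (hh), at 0.754 (0.588 to 0.952), and tsh-tio, whose interval is uncertain, with prd, esg and dac. The bins of tsh-tio also lie in the centromeric 2 Mb of 2L, which had 0.836 with its own arm 4 Mb or more from the end. However, tsh-tio with nub-pdm2 on the same arm had 1.41 (1.15 to 1.71). In the pilot library, where a pair held a median of 3 contacts, the median ratio was 0.874, above 45.3% of rotated lists. Over the 108 pairs on different chromosomes the deep median was 0.917, above 35.9% of rotated lists, and the pilot median 0.998, above 84.9%. In 5 of these the interval lay above 1, among them BX-C with inv-en at 2.08 (1.41 to 2.98), with a pilot ratio of 0.583 from 2 contacts, and BX-C with slp1-slp2 at 1.89 (1.26 to 2.73), with a pilot ratio of 1.40 from 5 contacts. In 4 it lay below 1, ANT-C with slp1-slp2 at 0.357 and with bi at 0.535, tsh-tio with the NK cluster at 0.399 and BX-C with dpp at 0.422. Intervals of single pairs, on the same arm or between chromosomes, cover counting error only and were not corrected for the number of pairs. How many would lie beyond 1 in rotated lists is not given. The 5 above and 4 below between chromosomes therefore do not show specific contacts. For the 20 loci outside the centromeric 2 Mb the eigenvector of the deep library was positive at 12, such as Dll (1.32), cad (1.32) and eve (1.30), and negative at 8, such as esg (-1.11), salm-salr (-0.770) and bi (-0.762). In the pilot library it was positive at all 20, from 0.230 at esg to 1.52 at eve. Of all bins outside the centromeric 2 Mb, 83.6% were positive in the pilot and 60.0% in the deep library, so the place of zero differed between the libraries.

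A few distant pairs of 80 kb bins on the same arm stood far above their distance in the deep library, and were named only where the pilot ratio was above 1 too, which 1 or 2 pilot contacts can meet. The pilot interval reached below 1 in 2 of the 10 named pairs on the same arm and in 7 of the 10 on different chromosomes. The highest joined 2R 4640001 to 4720000 with 2R 10880001 to 10960000, 6.24 Mb apart, with 456 contacts in the deep library, 28.7 times the number for that distance (26.2 to 31.5), and 29 in the pilot library, 21.2 times (14.2 to 30.4). On X, bins at 880001 to 960000 and 15920001 to 16000000 reached 24.5 (20.82 to 28.7) in the deep library and 4.54 (0.550 to 16.4) in the pilot library from 2 contacts. On 2L, bins at 20080001 to 20160000 and 21680001 to 21760000 reached 23.7 (22.0 to 25.5) and 11.8 (7.302 to 18.0). The others included 3L 12880001 to 12960000 with 20000001 to 20080000, at 11.2 and 9.05, and 3R 960001 to 1040000 with 7840001 to 7920000, at 10.7 and 4.10. All 10 named pairs on different chromosomes joined bins within 1 Mb of telomeric ends. The highest was that of the first 80 kb of 2L with the first 80 kb of 3L, at 55.2 (45.4 to 66.5) in the deep library and 7.14 (0.865 to 25.8) from 2 contacts in the pilot library. Reads shared by repeats were not tested for these pairs, and stay open as a source of their contacts.

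**Figure D4:**
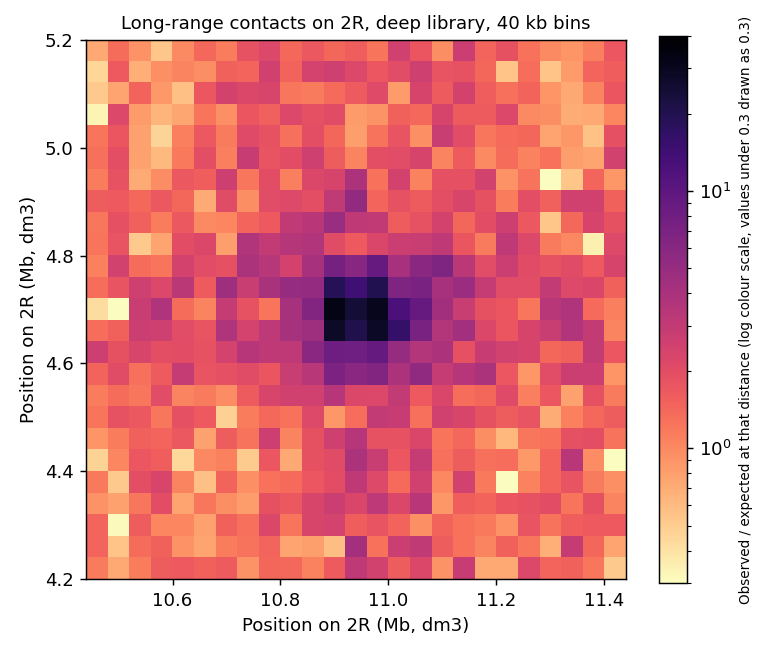
Contacts between 2 stretches of 2R in 40 kb bins of the deep library, position in Mb on both axes, coloured by observed over the number for that distance (log scale). The dark block at the centre holds 945 contacts in 9 bin pairs, 23.3 times the number for their distance.

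With the expected contacts and distance taken out, the contacts of the libraries correlated most at short range. Across pairs of 160 kb bins, Pearson r of the log2 distance-corrected contacts was 0.696 from 0.2 to 1 Mb (3655 pairs), 0.383 from 1 to 5 Mb, 0.192 over 5 Mb and 0.150 between chromosomes. Bin pairs are not replicates, and r at a given distance falls with the number of contacts per pair. Without the expected, r was 0.710, 0.686, 0.602 and 0.436 from the shortest to the between-chromosome class. Differences between bins, which the expected holds, then stay in both libraries, so these values do not show better agreement of contacts. With the expected and 80 kb bins r was 0.497, 0.227, 0.0948 and 0.0644.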

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

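All tests in this part were chosen after the results they bear on had been seen, except that of X contacts without the expected. For arm pairs, alignment, pooled ends and locus pairs, none had an interval above 1 in a library and below 1 in the other. For locus pairs the few pilot contacts almost fixed this outcome. A pilot interval left out 1 in 1 of the 56 pairs on an arm and in 0 of the 108 between chromosomes. Contacts within a single 80 kb bin are a signal that the comparisons of folding did not use, and were 40.7% of all contacts in the pilot library and 26.8% in the deep library.

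Contacts were lower within X and between X and autosomes than for autosomes. If X were present at 0.75 of the autosomal copy number, as in an equal mix of sexes, and contacts scaled with copy number alone, all ratios should lie at 0.75. That level leaves out contacts between homologous copies, which count as contacts within an arm, so the wide intervals within arms cannot decide. Within arms X over autosomes was 0.804 (95% interval 0.643 to 0.964) in the pilot and 0.706 (0.553 to 0.860) in the deep library, and between chromosomes 0.789 (0.737 to 0.840) in the deep library, all holding 0.75. The ratio between chromosomes in the pilot library, 0.836 (0.810 to 0.862), lay above it. Copy number alone at that level may therefore account for the ratio between chromosomes in the deep library but not for that in the pilot library. Observed contacts per bin pair gave 0.779 (0.706 to 0.851) in the deep library, which argues against the authors' expected contacts as the source there. In the pilot library this pooled ratio was not computed. Without the expected, pilot X with 2R turned to 1.04, and X with 2L, 3L and 3R stayed below 1, at 0.864, 0.918 and 0.972. The sex of the embryos is not in the labels.

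Of the contrasts, 5 in pooled contacts were weaker in the pilot than in the deep library, whereas contacts within over across domains were at 1.57 in pilot contacts at deep boundaries and 1.53 in deep contacts at pilot boundaries, which differ in both, and alignment of arms differed little, at 1.195 against 1.25. If a uniform share of random ligations diluted the pilot, the excess over 1 in the pilot divided by that in the deep library would be equal for all 5. It was 0.256 (SE 0.00799) for contacts of the same arm 1 to 5 Mb apart, 0.182 (SE 0.00815) over 5 Mb apart, 0.317 (SE 0.0698) for telomeric ends, 0.292 (SE 0.0625) for chromosome 4 with centromeric ends and 0.465 (SE 0.0318) for the arms of chromosomes 2 and 3. The last differed from the first by 0.209 (SE 0.0285), which argues against 1 uniform share as the whole cause, although telomeric ends and chromosome 4 lay within 1 SE of the first. Random thinning of the deep library to the pilot total kept at least 0.941 of each excess in 20 draws, as it must for a ratio of sums, so that it is no test of depth; embryo age, sequencer, effects of depth other than random sampling and a background that is not uniform stay open, and age was not tested apart from them.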

How the results depend on the processing

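No paired analysis was possible because each group has 1 library. Over all alternatives, 118 of 156 values of the main results stayed within their interval (1.5 times for counts). Of these, 11 were identical to the reported value and so no sign of stability. Among main results whose interval left out 1, 0 turned to its other side. Of the others, pilot ANT-C with BX-C went to 0.958 in 160 kb bins. The pilot trans median of the loci went to 1.12 with balancing and 1.02 without salm-salr and tsh-tio. The main results leave out, among others, pairs of arms of different chromosomes, those with X and the small chromosome included. Of 230 values outside the main results, 194 stayed within their interval and 25 moved out of it. Another 11, whose interval had left out 1, turned to its other side. All that turned were pairs of arms of different chromosomes. Alternatives not planned were those without the centromeric or the last 0.2 Mb of telomeric ends, without salm-salr and tsh-tio, and the slope without low bins. Those of the gene lists were not run. The mean correlation of eigenvectors in 160 kb bins, 0.550, counts as kept only because its sign was made positive after it was seen to be negative. The cause was not tested unless given.

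Without low bins the share within arms was 69.6% in the pilot and 80.7% in the deep library. From 0.4 to 10 Mb the mean autosomal slope was -0.603 and -0.667. With matrix balancing 2L-2R was 1.19 and 1.49, 3L-3R 1.15 and 1.30, 2R-3R turned to 0.9498 and 0.962, 3L-X to 1.03 and 1.06, 2L-X in the pilot to 1.00, and deep 2R-X went to 1.11; balancing sets each bin's total and so takes up differences of arms. Without the expected, pilot ratios turned to 0.948 for 2L-3L, 1.04 for 2R-X, 0.636, 0.770, 0.663 and 0.714 for chromosome 4 with 2L, 2R, 3L and 3R. Within 0.5 Mb of the ends the telomeric ratio was 2.52 and 7.26. Boundaries numbered 235 and 256 in 40 kb bins, 293 and 253 at depth 1.0, and 231 and 249 with 10 bins each side; the shared percentages were 47.1 and 48.1 in 10 kb bins with 10 bins each side, 46.4 and 53.8 at depth 1.0, and 51.9 and 48.2 with 10 bins each side. In 160 kb bins the same over opposite ratio by the pilot eigenvector was 1.22, the deep cis median of the loci 1.03, and ANT-C with BX-C 2.08 (2.53 with balancing). The ratio by the deep eigenvector was 1.31 without the centromeric 2 Mb, 1.04 in 160 kb bins and 1.09 with balancing. Correlations between libraries, from the shortest to the between-chromosome class, were 0.497, 0.227, 0.0948 and 0.0644 in 80 kb bins, and 0.674, 0.320, 0.135 and 0.0825 with the deep library thinned, so depth limits them. Without the expected, which leaves differences between bins in both libraries, the last 3 were 0.686, 0.602 and 0.436.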

Other observations

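The pairs and bins of this part, the tests of the 2R focus and the bounds of the count of expected totals were chosen after the results were seen. Of 205099 pairs of 80 kb bins over 1 Mb apart on an arm, 71 had a deep-library ratio of at least 5 with 20 or more contacts, and they involved 79 bins. Over these pairs together the pilot library had 472 contacts, 4.22 times the number for their distances (3.85 to 4.62). Adjacent bins of a focus count as separate partners here. The bin with the most partners, 5, was X 15920001 to 16000000. Adjacent bins of 3L, 12800001 to 12880000 and 12880001 to 12960000, had 4 partners each, as did X 880001 to 960000, X 17440001 to 17520000 and 2R 4560001 to 4640000. Among pairs outside the centromeric 2 Mb, in 32 both bins had a positive eigenvector in the deep library, in 15 both were negative and in 16 the signs differed.

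Between chromosomes and over 2 Mb from any end of an arm, among pairs with a pilot ratio above 1, the highest ratios in the deep library were those of 3L 13600001 to 13680000 with X 8160001 to 8240000, at 17.41 (12.3 to 24.0), with 2 contacts in the pilot library (4.46, 0.541 to 16.1), and of 2R 19120001 to 19200000 with 3L 15040001 to 15120000, at 16.4 (12.502 to 21.2). The latter had 13 contacts in the pilot library, 12.2 times the average (6.49 to 20.83).

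For the focus on 2R, an inversion would fill the 2 opposite quadrants around the focus that it joins, and their ratio to the other 2 quadrants was 0.921 (0.853 to 0.995) in the deep library, below the 2 set for an inversion. Reads shared by a repeat in the 3 central bins of either stretch would raise the rows and columns through the focus, so that a ring around it at 5.20 decides nothing; ring bins off those rows and columns, taken instead after that ring was seen, were 3.19 times (2.85 to 3.56) the level of outer bins, which argues against such a repeat as the whole cause, and wider repeats stay open. Of the 10 bins with the most partners, 3 had expected totals at or above the median of their arm (30%, exact interval 6.67 to 65.2%). Bins tied at 3 partners were taken in order of arm and position, so this count and the ratio below hold for these 10 only. A first rule, by which fewer than 50% counts for an understated expected, had read the count in its favour. The interval, adopted after the count was seen, leaves that open. With matrix balancing, a test set before its value was seen, the lowest ratio of these bins over their partners was 6.05 (lowest bound 5.37). The partners had been picked by a ratio of at least 5 in the same deep contacts, so a high value was in large part fixed. Because balancing rescales each bin as a whole, the value argues only against an expected understated over a bin's whole total. An expected understated for single pairs stays open. Contact in the nucleus between distant stretches may be a cause, as a hypothesis, and no biological explanation was tested.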
